A study of Mus musculus with 8 samples.

How the data were processed

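Whole kidneys of 8 mice were profiled by mRNA sequencing, 4 from Control mice and 4 from conditional knockout (cKO) mice. Per the labels, both groups carried floxed alleles of Xpr1 and received doxycycline at 2 mg/ml in the drinking water for 2 weeks from 8 weeks of age. The cKO mice also carried Pax8-rtTA, a doxycycline-dependent activator driven in kidney tubule cells, and LC1, which expresses Cre recombinase under that activator. Control mice were littermates without these transgenes, so the presence of Cre and rtTA and the loss of Xpr1 go together in this design. Libraries were made from 500 ng of total RNA with a stranded mRNA kit, per the labels' protocols. No batch, litter or pairing is given by the labels, and the animal numbers are not shared between groups.

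The deposited values are raw counts of reads per Ensembl gene, as the file headers and the whole numbers show. Per the submitters' processing notes, reads were trimmed with cutadapt 1.3, aligned with STAR 2.4.0g and counted with HTSeq 0.6.1 on genome build GRCm38. The annotation release, the strand setting of the counting and any filter are not given in the sources used here, so reads of overlapping and antisense genes may have been split in an unknown way. Each file listed 46517 genes. Gene symbols, positions and exonic lengths came from GENCODE vM21, which uses the same build; 46005 identifiers matched it and 512 did not. Closing lines that name no gene held reads without a feature, ambiguous reads and non-unique alignments, and made up 39.7% to 56.2% of each file's total. These lines were kept out of library sizes and tests.

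Reads with more than 1 alignment were not assigned to genes. Counts of near-identical copies therefore hold reads from their distinct parts alone. This may make members of the Cyp2d, Cyp4a, Cyp2j, Ugt2b, Ugt1a, Gsta, Slc22a, Slc6a20, Acaa1, Ifi27l2, globin and actin families uncertain. How similar the members of these families are was not examined. The total assigned to genes ran from 20366113 (cKO mouse KO16) to 26155030 (Control mouse C13). The spread between mice, not the counting error, set the precision: the common biological coefficient of variation was 0.386. No replicate pair looked like copies of the same library, because the chi-square per degree of freedom over genes was 7.48 for the closest pair of a group and 476 for the most distant.

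The comparison of cKO against Control used edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr (minimum count 10, minimum total count 15) and the quasi-likelihood F test on all 8 libraries without covariates. Adjusted p-values are Benjamini-Hochberg values over the 15382 genes tested, with a threshold of 0.05, and fold changes are given as log2 with the standard error (SE) derived from the F statistic. CPM values are TMM-scaled and given as mean ± SD over 4 mice; log2 CPM used a prior count of 2. Each mouse gave 1 library, so p-values measure the spread between these mice's libraries, which the labels call separate animals by name alone.

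A set of 38 gene lists was fixed before the data were examined. Lists were tested with camera (limma 3.58.1) with an inter-gene correlation preset at 0.01, and beside it with camera with an estimated correlation and with fry, each adjusted over the 38 lists. Camera compares a list with all other genes, and fry asks whether the genes of a list move on balance in a single direction. The genes named were also fixed beforehand by rule: Xpr1; the 10 that rose most and the 10 that fell most among genes with an adjusted p under 0.05, a mean of at least 1 CPM, groups that do not overlap and a symbol that is not a clone name or pseudogene; the members of each list with the smallest p, up to 4 where 3 or more passed and up to 2 otherwise; and 24 genes of phosphate handling, proximal tubule function and injury whatever their values. Members of a list that are named beyond this rule were chosen after their values were seen. Values of some genes that the rule selects are not reported here.

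The fit was tested on simulated counts for the same 15382 genes in 4 against 4 libraries. With no change simulated, 0 genes and 0 lists passed. Genes were drawn independently of each other, so this does not check the list test under the correlation of real genes. Splits of the real libraries that mix the groups, and may keep part of the genotype difference, passed up to 24 lists by camera with the preset correlation. Of 100 genes changed 2-fold 2% were called, and of 100 changed 4-fold 51% were called, with no call in the wrong direction and 3 calls among 15182 unchanged genes. In the simulation, changes near 2-fold were therefore mostly missed. Far fewer genes changed there than the 2170 called in the data, which makes the Benjamini-Hochberg threshold stricter, so these rates do not carry over to the real comparison.

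Alternatives fixed beforehand were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 1 CPM, a robust dispersion prior, 1 surrogate variable (sva 3.50.0), leaving mitochondrial genes out, adjusted p under 0.01, glmTreat against a fold change of 1.2, and leaving out each library in turn. Alternatives added after the libraries were seen left out KO16 and KO20, left out KO16, KO20 and C11, removed each library's loess trend (span 0.3) on gene length, or on length and GC content, and used the length slope of each library as a covariate. A covariate for sex was not used: every library had at most 5 reads of Xist, the X-inactivation transcript, and at least 409 of the Y-linked gene Ddx3y, which leaves 1 sex. Near-identical nuclear copies of mitochondrial genes were sought with blastn among the annotated transcripts.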

Results

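The kidneys of 4 Control mice (C10, C11, C13 and C14) and 4 cKO mice (KO16, KO18, KO19 and KO20) were compared after 2 weeks of doxycycline, to ask what the loss of XPR1, a retrovirus receptor and phosphate exporter, from the nephron changes in renal gene expression. Reads assigned to genes ranged from 20366113 (KO16) to 26155030 (C13) per library. Of the 46517 genes listed, 15382 had enough reads to be tested.

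Xpr1, the targeted gene, fell to 16.6 ± 9.43 CPM in cKO kidneys from 104 ± 19 CPM in Control kidneys (SD, n = 4 mice each), a log2 fold change of -2.65 (SE 0.44, adjusted p = 0.00491). The Control libraries held 80.2 to 126 CPM and the cKO libraries 5.74 to 26.5 CPM, so each library followed its label. The gene (ENSMUSG00000026469) lies on the minus strand of chromosome 1 from 155275701 to 155417415 in GRCm38. Exon 2, the floxed exon, spans 155384611 to 155384662 (52 bp), whereas the last exon of the main transcript, which holds the 3' UTR, spans 5370 bp. The gene-level count thus came mostly from sequence outside the deleted exon and gives no direct measure of how many cells lost it.

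The loss of Xpr1 went with a broad change in the kidney transcriptome. A total of 2170 genes changed, 14.1% of those tested, with 1154 higher and 1016 lower in cKO kidneys, and 1824 of them changed at least 2-fold. At least 4-fold changes were found upward in 366 genes and downward in 261. The genes that fell most included Slc22a8, an organic anion transporter of the proximal tubule (293 ± 189 against 4.88 ± 4.07 CPM), the cytochromes Cyp2e1 (2371 ± 325 against 61.2 ± 28.2 CPM) and Cyp2d12 (82.9 ± 18.8 against 0.326 ± 0.213 CPM), and the monocarboxylate transporter family member Slc16a14 (49.0 ± 13.5 against 0.769 ± 0.862 CPM). Fcamr (log2 fold change -5.83), Dpys, an enzyme of pyrimidine breakdown (-5.55), Hrg (-5.18), Nepn (-5.14), Synpr (-5.98) and Cyp4a12a (-5.25) completed the 10 that fell most.

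Genes that rose most were nearly silent in Control kidneys. Spaca7, named for the sperm acrosome, rose to 30.9 ± 20.9 from 0.207 ± 0.296 CPM and Psrc1, a spindle-associated protein, to 28.3 ± 11.9 from 0.686 ± 0.593 CPM. Sult4a1, a sulfotransferase family member, rose to 15.3 ± 2.03 from 0.124 ± 0.158 CPM, and the vomeronasal receptor gene Vmn1r32 to 7.47 ± 2.88 from 0.113 ± 0.167 CPM. Casp14 (log2 fold change 5.64), Ifi27l2b (5.73), Ugt2b35 (5.12) and Acta1, skeletal muscle actin (5.26), rose from at most 14 reads over the 4 Control libraries. The cytokine gene Il1f6 and S100a3 each had 2 reads over all Control libraries, against 316 and 230 over the cKO libraries, and the scaled read ratios were 135 (95% exact binomial counting interval 37.1 to 1120) and 98.3 (26.9 to 816). These intervals cover counting error alone, and without C10 the adjusted p of Il1f6 was 0.0516. Counts of Cyp2d12, Cyp4a12a, Ugt2b35, Ifi27l2b and Acta1 may be uncertain, because they belong to gene families and reads shared with related genes were not assigned. How much sequence they share was not examined. The groups did not overlap for 2123 of the 2170 changed genes and for 22.8% of all tested genes, where chance gives 2.86%.

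Libraries of the same group differed from each other. In KO16 and KO20, which also held the least Xpr1, reads leaned most to short transcripts. Refits without these libraries leave out both features, which were not told apart. The shortest sixth of genes lay 1.1 and 0.557 above the mean of the Control libraries (log2), and the longest sixth -0.978 and -0.452 from it. C10 leaned the same way by less (0.281 and -0.255). C11 leaned to long transcripts, at -0.416 and 0.331, and so did KO18 (-0.28 and 0.346) and, less so, KO19 (-0.134 and 0.225). The first principal component (54.2% of the variance) placed KO16 at 112, KO20 at 80.8 and C11 at -86.1, with the other libraries between -43 and 1.93. Scaling by library totals alone put the median log2 fold change of all genes at 0.344 and gave 2374 higher (81.2%) and 548 lower genes, and upper-quartile scaling put it at 0.14 and gave 1460 higher (63.9%) and 826 lower. Without C10, C13, C14 or KO20 the total was 1436, 1106, 1200 or 1311 genes, and without KO16, KO20 and C11 together it was 9175, among them 2110 of the 2170.

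**Figure D1:**
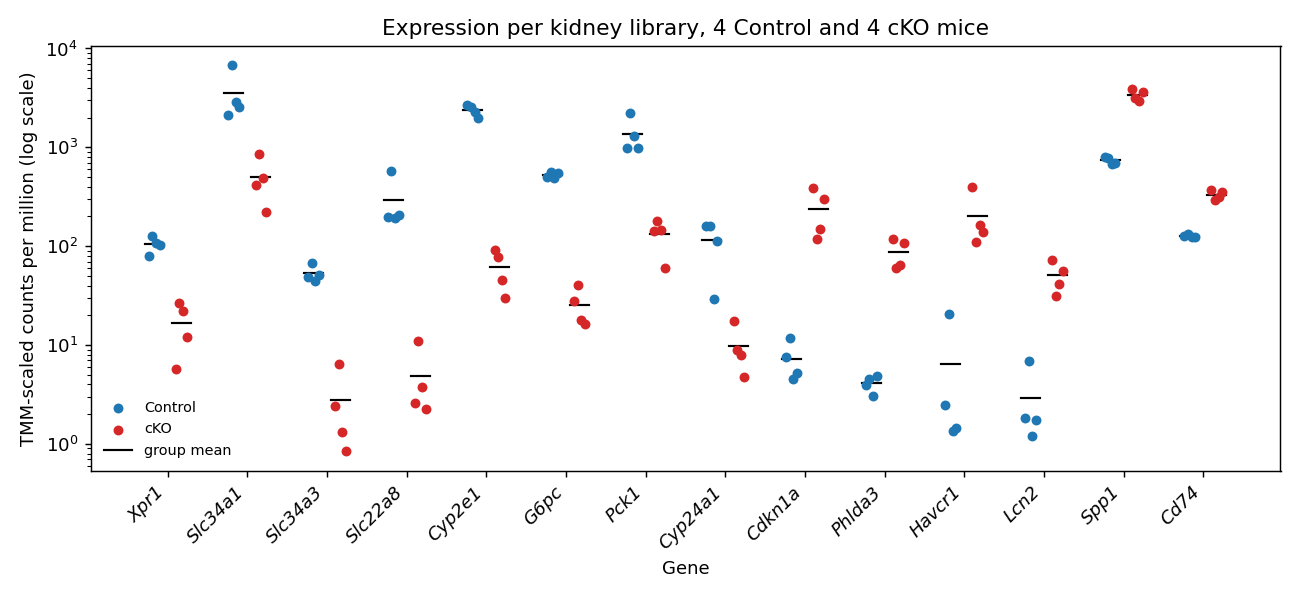
TMM-scaled CPM (log axis) of 14 genes in each kidney library; points are mice (4 Control in blue, 4 cKO in red) and black lines are group means. For every gene drawn the groups are apart, with Xpr1 at 80.2 to 126 CPM in Control and 5.74 to 26.5 CPM in cKO libraries.

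Sodium-phosphate cotransport genes of the proximal tubule were lower in cKO kidneys. Slc34a1, which encodes the main cotransporter NaPi-IIa, fell by 2.84 on the log2 scale (SE 0.52, adjusted p = 0.00736; 3571 ± 2152 against 499 ± 269 CPM) and Slc34a3, encoding NaPi-IIc, had a log2 fold change of -4.25 (SE 0.61, adjusted p = 0.0024; 53.2 ± 10.2 against 2.77 ± 2.55 CPM). The parathyroid hormone receptor gene Pth1r fell by 1.16 (adjusted p = 0.00492). The ubiquitous transporter genes Slc20a1 and Slc20a2 had log2 fold changes of -0.12 and -0.91 (adjusted p = 0.874 and 0.0743), the scaffold gene Slc9a3r1 -0.13 (0.795) and the FGF23 coreceptor gene Kl -0.85 (0.251). Of 19 tested members of the phosphate list 7 fell, Slc17a3, Slc17a1, Slc37a4 and Pdzk1 among them, 1 rose (Slc17a2, 2.28) and 11 did not pass; adjusted over the list alone 8 fell and 2 rose. The list was lower by camera (adjusted p = 0.00278; adjusted p = 0.438 with an estimated correlation). The list call depended on KO16 and KO20: without both, its median moved from -0.619 to -0.202 and its adjusted p to 0.0956 (-0.0703 and 0.0144 without C11 alone). Without KO16, KO20 and C11 together the list had no direction, with 7 members higher, 8 lower and a median of -0.00596 (adjusted p = 0.251 by camera). Slc34a1, Slc34a3 and Pth1r kept their calls throughout.

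Of the genes that handle calcium and vitamin D, Cyp24a1, the enzyme that inactivates vitamin D, fell to 9.78 ± 5.50 from 116 ± 61.8 CPM (log2 fold change -3.57, SE 0.60, adjusted p = 0.00491). Cyp27b1, the activating enzyme, stood at 4.43 ± 2.46 and 1.79 ± 1.31 CPM (-1.29, adjusted p = 0.188). The calcium channel gene Trpv6 rose by 1.51 (adjusted p = 0.00517). In this list of 17, 2 members rose (Trpv6 and Gc, the vitamin D-binding protein gene, 1.66), 2 fell (Cyp24a1 and Cldn2, -0.89) and 13 did not pass, with the same counts adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.8). The call of Gc was lost without C11, C13, C14, KO16 or KO20 (adjusted p up to 0.108, without C13), and that of Cldn2 without C10 (0.0623), C13 (0.0703), C14 (0.0715) or KO20 (0.066).

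Other transport genes of the proximal tubule fell widely. Among 34 carriers of organic anions, organic cations, urate and carboxylates, 24 fell, 0 rose and 10 did not pass (27 fell adjusted over the list alone), including Slco1a1 (-3.54), the sulfate cotransporter gene Slc13a1 (-2.48) and Slc22a30 (-2.51). The list was lower at adjusted p = 2.53e-21, and at adjusted p = 0.0427 with an estimated correlation. Among 26 glucose and amino acid transport genes 12 fell and 1 rose, with 13 not past the test; adjusted over the list alone 14 fell and 3 rose. Slc6a19, the neutral amino acid carrier B0AT1, fell by 1.96 (SE 0.33, adjusted p = 0.00515), Slc7a9, the cystine carrier subunit, by 2.07 (SE 0.21, adjusted p = 0.000671), and Slc7a7 by 1.74 (adjusted p = 0.00262). Slc5a2, the SGLT2 glucose carrier, fell by 1.57 (adjusted p = 0.0221; 0.056 without KO19 and 0.0772 without KO20), whereas Slc5a1 had a value of -0.24 (adjusted p = 0.586). The member that rose was Slc7a12 (2.93). This list was lower at adjusted p = 2.41e-07, and adjusted p = 0.318 with an estimated correlation.

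Of 16 genes for sodium, bicarbonate and water transport, 5 fell (Car14, Kcnj15, Aqp11, Slc26a6 and Cldn2), Aqp7 rose and 10 did not pass; adjusted over the list alone 6 fell and 1 rose. The carbonic anhydrase gene Car14 fell by 3.07 (adjusted p = 0.000755) and the potassium channel gene Kcnj15 by 1.95 (adjusted p = 0.00638). The sodium-hydrogen exchanger gene Slc9a3 had a log2 fold change of -1.51 (adjusted p = 0.224), the bicarbonate cotransporter gene Slc4a4 -1.2 (0.0633) and the water channel gene Aqp1 -0.21 (0.582). The list was lower (adjusted p = 0.000935; adjusted p = 0.292 with an estimated correlation), and its median moved from -0.888 to -0.356 without KO16, KO20 and C11. The signs of Aqp1, Slc5a1, Slc9a3r1 and Slc20a1, none of which passed, are not settled: they turned positive with library totals alone, which raise all genes alike. That of Slc20a1 also turned without C11, KO16 or KO20, and that of Slc9a3r1 without C11 or KO20. Without KO16, KO20 and C11 together Slc20a1 was called higher (0.506, adjusted p = 0.0204) and Slc5a1 stood at 0.115 (0.429). Calls of Aqp11 (0.0636), Slc26a6 (0.057) and Cldn2 (0.066) were lost without KO20, that of Slc26a6 also without KO19 (0.0503), and that of Cldn2 also without C10 (0.0623), C13 (0.0703) or C14 (0.0715).

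Genes of endocytic protein uptake changed in part. Lrp2, encoding the receptor megalin, fell by 1.81 (SE 0.44, adjusted p = 0.0244; 0.0537 without KO19 and 0.0615 without KO20), and Cubn, encoding cubilin, had a value of -1.76 (SE 0.54, adjusted p = 0.0609). Of 24 list members 4 fell (Lrp2, Lrpap1, Fcgrt and Atp6v0a4), 1 rose (Ctsd, the lysosomal protease cathepsin D) and 19 did not pass, against 6 and 1 adjusted over the list alone. The list did not pass by camera (adjusted p = 0.0923; 0.0228 without KO16) and was lower by fry (adjusted p = 0.0215). Without a single library the adjusted p of Lrpap1 reached 0.13 (KO20), that of Fcgrt 0.124 (KO20) and that of Ctsd 0.112 (C13).

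The enzyme complement of the proximal tubule was lower as a group. Of 44 enzymes and regulators 29 fell, 0 rose and 15 did not pass; adjusted over the list alone 38 fell. The list median was -1.55 (adjusted p = 1.36e-34; adjusted p = 0.0214 with an estimated correlation). Cyp4b1 fell to 302 ± 47.5 from 3344 ± 663 CPM and Inmt, a methyltransferase, to 114 ± 35.7 from 1461 ± 270 CPM, and Agxt2 fell by 2.79 (SE 0.20, adjusted p = 0.000215). Hnf4a, a transcription factor of proximal tubule identity, fell by 1.55 (SE 0.41, adjusted p = 0.0363), with adjusted p-values of 0.0549 to 0.0927 when C10, C11, C13, C14, KO16 or KO20 was left out.

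Glucose production and fatty acid oxidation genes followed the same direction. G6pc, glucose-6-phosphatase, fell by 4.36 (SE 0.34, adjusted p = 0.000215; 525 ± 35.7 against 25.5 ± 11 CPM) and Pck1, the rate-limiting enzyme of gluconeogenesis, by 3.39 (SE 0.43, adjusted p = 0.00142; 1377 ± 592 against 132 ± 50.1 CPM). In the gluconeogenesis and ammonia list 9 of 19 fell, 0 rose and 10 did not pass, with 9 fallen and 1 risen adjusted over the list alone (adjusted p = 2.5e-06; adjusted p = 0.273 with an estimated correlation). Its median was -0.382, and lay between -0.158 without KO20 and -0.737 without KO16. In the fatty acid oxidation and peroxisome list 16 of 35 fell, 0 rose and 19 did not pass, with 18 fallen adjusted over the list alone. The smallest p-values were those of Acsm5 (-1.93), Ehhadh (-1.32), catalase, Cat (-1.19), and Acaa1b (-1.16). That list was lower at adjusted p = 7.57e-09, and adjusted p = 0.21 with an estimated correlation.

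Respiratory chain genes gave a different picture. None of the 45 nuclear-encoded members passed the edgeR test, nor adjusted over the list alone, the list median was 0.378 and the list did not pass (adjusted p = 0.586); Ndufs1 had a value of -0.72 (adjusted p = 0.0715) and Sdha -0.80 (0.162). This list depended on KO16 and KO20, which lean most to short transcripts and also held the least Xpr1. Without KO16 alone its median was -0.136 (adjusted p = 0.0803), without KO16 and KO20 it was -0.479 (adjusted p = 9.77e-05), and without C11 as well -0.679, with 43 of 45 members lower. With 1 surrogate variable 14 members rose and 2 fell (median 0.175, adjusted p = 0.29), and with the length trend removed the median was 0.0363 (adjusted p = 0.813). The 7 tested mitochondrially encoded genes, of which 0 passed and 0 passed adjusted over the list alone, were lower as a list (median -0.557, adjusted p = 0.0394; adjusted p = 0.573 with an estimated correlation), a call lost without C14 (0.057), KO16 (0.0653) or KO19 (0.0798), with the length trend (0.0534) or length and GC trends (0.0961) removed, with the length slope (0.161) or 1 surrogate variable (0.146) as a covariate, with no filter (0.0863) and by fry (0.109). Without KO20 its median was -0.92 (adjusted p = 0.000329). Among its members mt-Nd5 had a value of -1.34 (adjusted p = 0.093) and mt-Nd2 -0.75 (0.145).

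Tubule injury genes were higher in cKO kidneys. Havcr1, encoding kidney injury molecule 1, rose to 202 ± 129 from 6.46 ± 9.42 CPM (log2 fold change 4.96, SE 1.02, adjusted p = 0.0122), and Lcn2, encoding NGAL, to 50.6 ± 18 from 2.94 ± 2.71 CPM (4.10, SE 0.60, adjusted p = 0.00269). Spp1, osteopontin, rose to 3401 ± 435 from 737 ± 63.1 CPM. Of the Control libraries, C11 was highest for Havcr1 (20.6 CPM, against 1.35 to 2.46 in the others) and Lcn2 (6.98 against 1.22 to 1.83). For Spp1, C11 (775 CPM) lay within the range of the other Control libraries (671 to 805). Of 31 members 21 rose, 1 fell (Fgb, -2.16) and 9 did not pass; adjusted over the list alone 25 rose and 1 fell. The urokinase receptor gene Plaur (2.86), Anxa3 (2.74) and Cp (2.06) were among those that rose. The list was higher at adjusted p = 1.57e-17, and adjusted p = 0.184 with an estimated correlation. Its median was 1.85, and 1.2 without KO16, KO20 and C11.

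Targets of the tumour suppressor p53 rose together. The cell cycle inhibitor gene Cdkn1a rose to 240 ± 130 from 7.30 ± 3.24 CPM (log2 fold change 5.04, SE 0.52, adjusted p = 0.000671), Eda2r to 53.3 ± 17.7 from 1.92 ± 0.518 CPM (4.79, SE 0.34) and Phlda3 to 87.7 ± 29.8 from 4.11 ± 0.827 CPM (4.41, SE 0.33), the latter 2 at adjusted p = 0.000215. Of 16 members 12 rose, 0 fell and 4 did not pass (13 rose adjusted over the list alone), and the list was higher with both forms of camera (adjusted p = 1.79e-16; adjusted p = 0.00511 with an estimated correlation). Cell cycle genes rose as well, 11 of 35 with 0 lower and 24 not past the test (17 adjusted over the list alone), and the smallest p-values were those of the spindle factor gene Tpx2 (3.27, SE 0.34), Ccne1 (2.27), Aurkb (1.89) and Aurka (1.79). The list was higher at adjusted p = 1.14e-08, and adjusted p = 0.145 with an estimated correlation.

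Stress genes were mixed. Atf3 (3.80) and Egr2 (2.19) were 2 of 4 immediate early genes that rose among 17, with Ier3 and Fosl1, 0 fell and 13 did not pass (5 rose adjusted over the list alone; list adjusted p = 0.00917, 0.079 without KO18, 0.0628 with length and GC trends removed, 0.11 by fry, and adjusted p = 0.565 with an estimated correlation). The calls of Ier3 and Fosl1 were lost without C13 (0.0683 and 0.127) or C14 (0.0649 and 0.122), and that of Fosl1 also without C10 (0.11), KO18 (0.0933), KO19 (0.068) or KO20 (0.0779). In the integrated stress and unfolded protein response list of 26, 7 rose, 2 fell and 17 did not pass (8 and 3 adjusted over the list alone). Gdf15 (3.05), the serine synthesis gene Phgdh (1.74) and Aldh18a1 (1.45) rose, while Shmt2 (-1.52; adjusted p 0.0591 without KO20) and Herpud1 (-0.90) fell. This list passed (adjusted p = 0.035; adjusted p = 0.438 with an estimated correlation) but not without C11 (0.141), C14 (0.0604) or KO16 (0.136), nor with the length trend (0.0683) or length and GC trends (0.147) removed or the length slope as a covariate (0.0897). Its median went from 0.623 to 0.246 without KO16 and KO20 (adjusted p = 0.263). Of 21 NRF2 targets 6 rose and 3 fell, with 12 not past the test (8 and 4 adjusted over the list alone), Gsta1 (4.32) and the epoxide hydrolase gene Ephx1 (2.56) upward and Ugt1a6a (-1.96) and Me1 (-1.15; adjusted p 0.0506 without KO20) downward; the list did not pass (adjusted p = 0.395).

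Markers of macrophages and dendritic cells were higher, 16 of 19 rising, 0 falling and 3 not passing, with 16 also adjusted over the list alone. The list median was 1.85, and 1.2 with 14 risen without KO16 and KO20. Cd74, the MHC class II invariant chain, rose to 332 ± 36.3 from 127 ± 4.03 CPM, Itgam by 1.93, Adgre1 by 1.67 and Cx3cr1 by 1.34. The list was higher at adjusted p = 6.87e-13, and adjusted p = 0.184 with an estimated correlation. Of 19 chemokine, cytokine and adhesion genes 10 rose, 0 fell and 9 did not pass (11 adjusted over the list alone), with the smallest p-values for Tlr2 (2.05), Socs3 (2.12), Cxcl2 (3.68) and the macrophage growth factor gene Csf1 (1.81). That list was higher with both forms of camera (adjusted p = 3.52e-08; adjusted p = 0.0327 with an estimated correlation). Among 22 collagen, matrix and fibroblast genes 4 rose (Mgp, 2.48; Lox, 1.97; Col3a1, 1.53; Dcn, 1.45), 0 fell and 18 did not pass, against 11 adjusted over the list alone (list adjusted p = 3.17e-05; adjusted p = 0.273 with an estimated correlation). Without C13 the adjusted p of Lox was 0.0687 and that of Dcn 0.071, and that of Lox was 0.0594 without C14.

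Interferon response genes, of which Irf7 (1.64) and Ifi27l2a (2.54) rose, 0 fell and 19 did not pass among 21 (6 rose adjusted over the list alone), were higher as a list (adjusted p = 0.0179; adjusted p = 0.376 with an estimated correlation). Without KO16 and KO20 the list median moved from 0.609 to 0.31 and its adjusted p to 0.211, without KO20 alone the latter was 0.0547, and the adjusted p of Ifi27l2a was 0.352 without both and 0.0808 to 0.129 without any of C10, C11, C13, KO16, C14 or KO20. Lymphocyte and neutrophil markers did not pass as a list (adjusted p = 0.113; 0.0488 without C10 and 0.0193 without KO19). Without KO16 and KO20 the median turned from 0.556 to -0.063 (adjusted p = 0.963). Of 20, Ighm (1.80) and Cd4 (1.12) rose, 0 fell and 18 did not pass, with 1 risen adjusted over the list alone. The call of Cd4 was lost without C10 (0.102), C11 (0.0654), C13 (0.139), C14 (0.102), KO18 (0.0932) or KO20 (0.103).

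Markers of nephron segments beyond the proximal tubule did not pass as lists by camera. Of 10 loop of Henle markers 1 rose, Bst1 (3.56, SE 0.38, adjusted p = 0.000724), 0 fell and 9 did not pass, and Kng2 had a value of 0.51 (adjusted p = 0.29); the list median was 0.217 (adjusted p = 0.139 by camera and 0.0356, higher, by fry). None of 10 distal convoluted and connecting tubule markers passed the edgeR test (median 0.00592, adjusted p = 0.98), with Klk1 at 0.69 and Trpv5 at 0.45, nor did any of 13 intercalated cell markers (median 0.0263, adjusted p = 0.98), with Atp6v1g3 at 0.93 and Slc4a1 at -0.999. Of 12 principal cell markers the water channel gene Aqp2 rose (1.10), Aqp3 fell (-1.03) and 10 did not pass (median 0.09, adjusted p = 0.805). Without KO16, KO20 and C11 the values of Kng2 and Atp6v1g3 turned to -0.112 and -0.0926. Aqp2 lost its call without C13 (0.0527) and Aqp3 without C13 (0.0594), C14 (0.053), KO19 (0.0634) or KO20 (0.0901). None of 12 podocyte markers passed the edgeR test (median -0.344, adjusted p = 0.462). That median was 0.166 without C11, and 0.363 with 5 higher and 1 lower without KO16, KO20 and C11. Of 15 endothelial markers Sox18 fell (-0.88), 0 rose and 14 did not pass (median -0.411, adjusted p = 0.0948; 0.0335 without C10; median -0.226 without KO16 and -0.19 without KO16 and KO20), with Kdr at -0.98 (adjusted p = 0.0717). The call of Sox18 was lost without C13 (0.0964), C14 (0.0966), KO18 (0.0646), KO19 (0.0576) or KO20 (0.122). Counts adjusted over the list alone were the same for these 6 lists.

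Of 25 cholesterol genes 6 fell, among them Cyp51 (-1.62), Hmgcs1 (-1.59) and Insig1 (-1.31), 2 rose, Pmvk (0.90) among them, and 17 did not pass (8 fell and 2 rose adjusted over the list alone). The list was lower by fry (adjusted p = 0.0316), missed the threshold by camera (adjusted p = 0.0565) and passed it without C10 (0.0402), C14 (0.0296), KO16 (0.00826) or KO19 (0.0427). Hmgcs1 lost its call without C13 (0.0546) or KO20 (0.0522), and Pmvk without C10 (0.0547), C13 (0.0731) or C14 (0.0766). Of 14 osmolyte and water genes Slc6a12 (2.25), the heat shock gene Hspa1b (1.64) and Aqp2 rose, Aqp3 fell and 10 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.139 by camera, 0.0284 without KO16 and KO20, and 0.0197, higher, by fry). Of 9 renin-angiotensin and hormone genes Agt rose (1.28), 0 fell and 8 did not pass, against 2 risen and 5 fallen adjusted over the list alone (list adjusted p = 0.831); Ren1 had a value of 0.79 (adjusted p = 0.239) and Ace -1.70 (adjusted p = 0.0814).

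Of 18 glycolysis genes Hk2 (1.17), Pkm (0.94) and Slc16a3 (1.2) rose, also adjusted over the list alone, 0 fell and 15 did not pass, with Slc2a1 at 0.57 (list adjusted p = 0.187). Each of these 3 calls was lost without C10 (0.134, 0.107 and 0.0747), C13 (0.149, 0.126 and 0.1), C14 (0.153, 0.12 and 0.0576) or KO20 (0.0866, 0.0696 and 0.0705), those of Pkm and Slc16a3 without C11 (0.0603 and 0.0612), and that of Hk2 without KO16 (0.054), KO18 (0.09) or KO19 (0.0857). Of 17 circadian clock genes Hlf (-1.80) and Bhlhe40 (-1.38) fell, also adjusted over the list alone, 0 rose and 15 did not pass (list adjusted p = 0.178). Without KO20 their adjusted p-values were 0.0544 and 0.0896, and that of Bhlhe40 was 0.0662, 0.0715, 0.0961 and 0.0666 without C10, C11, C13 and C14.

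Sex-dimorphic kidney genes fell in these male libraries. Of 14 tested members 7 fell, 1 rose (Slc7a12) and 6 did not pass (9 and 1 adjusted over the list alone), with the smallest p-values for Slco1a1 (-3.54), Cyp2j13 (-2.90), Cyp4a12a and Slc22a28 (-2.14), and the list was lower with both forms of camera (adjusted p = 1.97e-09; adjusted p = 0.0329 with an estimated correlation). Several of its members are also proximal tubule genes, and Slco1a1, Slc22a28, Kap, Cyp7b1, Acsm3, Cyp4a14 and Slc7a12 stood in other lists too.

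Markers of tissues next to the kidney varied between libraries. Of 10 urothelial and papillary markers Upk3b rose (1.34), 0 fell and 9 did not pass (2 rose adjusted over the list alone), with Psca at 1.54 (adjusted p = 0.0529). This list passed (adjusted p = 0.0156; adjusted p = 0.573 with an estimated correlation), but not without KO16 and KO20 (0.434), C11 (0.0987) or KO16 (0.0924), nor with length and GC trends removed (0.101) or the length slope as a covariate (0.0747) or by fry (0.114), and Upk3b lost its call without C13 (0.072) or KO20 (0.0593). Of 10 adipocyte markers Lpl (-2.25) and Pck1 fell, both of which the kidney expresses itself, 0 rose and 8 did not pass (2 rose and 2 fell adjusted over the list alone), while the list median was 1.96 (adjusted p = 0.98). Of 8 blood and muscle markers Acta1 rose, 0 fell and 7 did not pass, also adjusted over the list alone. The median (-0.101) and the test pointed down and the mean (0.467) up (adjusted p = 0.926). Without KO16 the median was -0.73 (adjusted p = 0.0969), and without KO16 and KO20 the list was lower at 0.00589. Of 3 tested adrenal markers Mc2r rose (2.14; lost without C10, 0.0658, C13, 0.0725, C14, 0.0728, or KO20, 0.064), with Akr1b7 at 0.79 (adjusted p = 0.186). None fell, the count was the same adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.264) but was higher by fry (0.0174).

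**Figure D2:**
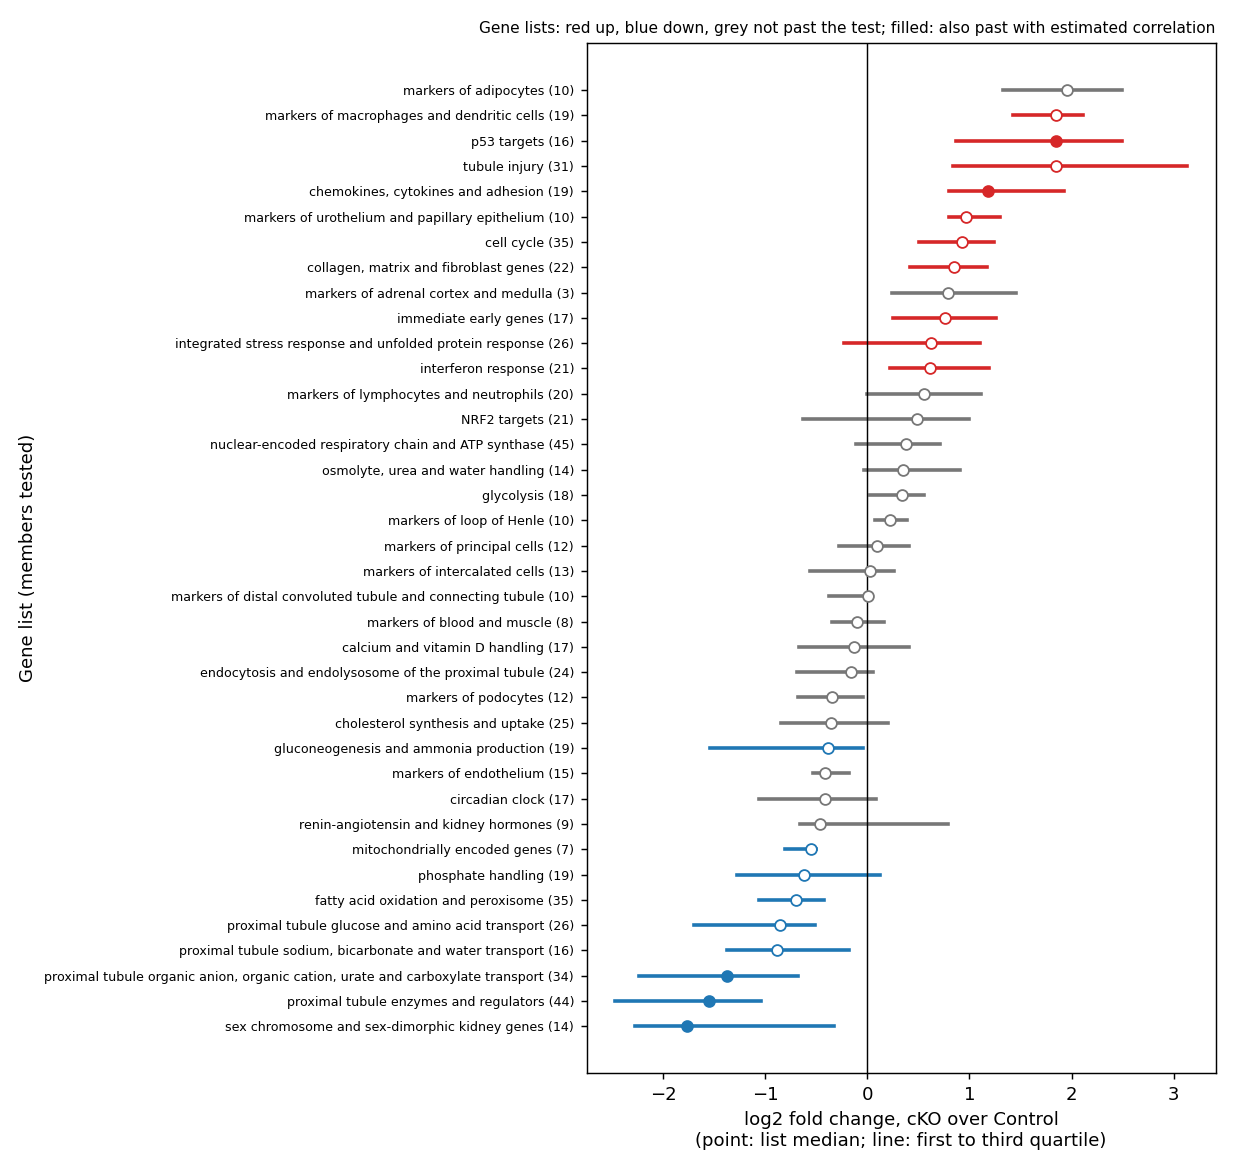
Median (point) and interquartile range (line) of the log2 fold change of cKO over Control for the tested members of each of the 38 gene lists. Of these, 10 passed upward (red) and 9 downward (blue) by camera with the preset correlation, 19 did not pass (grey), and 5 also passed with an estimated correlation (filled points).

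**Figure D3:**
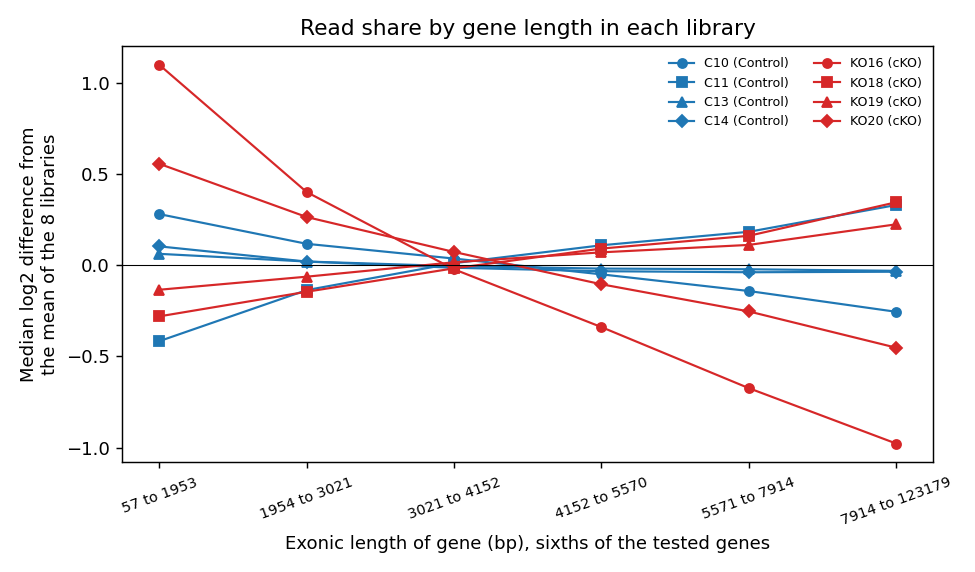
Median log2 difference of each library from the mean of the Control libraries, for sixths of the tested genes ordered by exonic length in bp (Control in blue, cKO in red). The axis label names the mean of the 8 libraries, but the values were taken from the Control mean. KO16 runs from 1.1 in the shortest to -0.978 in the longest sixth, and C11 runs the other way, from -0.416 to 0.331.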

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

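The gap statistic (the distance of the highest or lowest of 4 libraries from its neighbour over the whole range, with Dixon's 95% critical value for 4 libraries as threshold) was fixed before the data were examined; the measures per library were chosen afterwards. It was computed for 296 pairs of a named gene and a group and exceeded the threshold in 28, where chance passes about 1 in 20; the pairs share libraries and are not independent.

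C11 stood apart from the other Control libraries in 13 of the 28 pairs. It was highest for Slc22a8 (0.95), Sult4a1 (0.97), Csf1 (0.837), Lrp2 (0.988), Pkm (0.943), Fosl1 (1), Trpv5 (0.842), Ephx1 (0.883), Slc7a7 (0.842), Slc26a6 (0.832), Kl (0.877) and Slc5a2 (0.951), and lowest for Inmt (0.965). Its share of reads from Kap, an abundant androgen-dependent transcript of the proximal tubule, was also lowest, 2.49% against 6.85% to 7.67% (gap 0.842). C10 was highest for Il1f6 (1), Atf3 (0.847) and Ier3 (0.935) and lowest for Insig1 (0.845) and mt-Nd5 (0.885), and C13 was lowest for Cd4 (0.87).

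Among the cKO libraries, KO20 was lowest for Cyp51 (0.938) and Cat (0.892) and highest for Eda2r (0.901) and Cp (0.937). KO16 was highest for Pkm (0.889) and Me1 (0.95), KO18 was highest for Nepn (0.891) and lowest for Cx3cr1 (0.953), and KO19 was lowest for Inmt (0.867).

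Reads outside the gene counts also set libraries apart. The share of alignments that were not unique was 49.8% in KO16 and 53.4% in KO20, above the 33.7% to 43.3% of the Control libraries. Ambiguous reads made up 0.755% in KO16 and 0.614% in KO19, against at most 0.606% in Control libraries, and reads without a feature 5.43% in KO18, against at most 5.34%.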

How the results depend on the processing

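Alternatives that left out more than 1 library or dealt with gene length were chosen after the libraries were seen; the others were fixed beforehand. Xpr1 kept its direction and call in each of the 23 refits, at -2.98 to -2.37 without a single library. No gene called in cKO against Control changed direction while called in any of them. Of 147 other named genes 119 were called, 87 of them in all 23 refits, and 32 lost the call in at least 1; the stricter threshold and glmTreat were not counted here. Of the 28 not called, 22 were called in at least 1.

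The count of 2170 changed genes (1154 higher, 1016 lower) lay between 1106 and 2697 when a single library was left out (1106 without C13, 1200 without C14, 1311 without KO20, 1436 without C10), with 531 to 1363 higher, 566 to 1334 lower and 1094 to 1977 changed at least 2-fold. It was 3267 with DESeq2 (1764 higher), 6127 with 1 surrogate variable (3077 higher, 3050 lower) and 865 at adjusted p under 0.01 (415 and 450). With library totals alone 2374 were higher and 548 lower. Without KO16, KO20 and C11 it was 9175 (4689 higher, 4486 lower; 3465 at least 2-fold), with length and GC trends removed 3559 (1815 and 1744), and with the length slope as a covariate 5111 (2550 and 2561). The stricter threshold lowers the count by construction; the cause of the other differences was not tested. RLE factors (2086), limma-voom (2095), no filter (2003), a mean of at least 1 CPM (1908), a robust prior (2102) and leaving out KO16 and KO20 (2645) stayed within 1.5 times.

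Of 19 lists past camera (17 to 22 without a single library), 5 passed with an estimated correlation, and 21 lists passed by fry. The respiratory chain list (0.378, not past) turned to -0.479 without KO16 and KO20 and to -0.679 without C11 as well, where Slc20a1 (-0.12, not past) turned to 0.506 (adjusted p = 0.0204); the cause was not tested. In the simulation 2% of 2-fold changes were found, but fewer genes changed there than were called here, so this rate does not carry over. Changes of that size may still be missed, although genes were called down to an absolute log2 fold change of 0.58.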

Other observations

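The tests in this part were chosen after the results were seen, except those of the mitochondrial gene copies and of the list counts with an estimated correlation.

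The adipocyte transcripts Adipoq and Cfd were highest in KO16 and KO20, which lean most to short transcripts, whereas Lpl and Pck1 of the same list were not. Adipoq, the adipocyte hormone adiponectin, stood at 25.8 CPM in KO16 and 25.3 in KO20, against 0.928 in KO18, 7.39 in KO19 and 0.522 to 3.96 in Control libraries. Cfd, adipsin, had 71.3 and 74.3 CPM in KO16 and KO20, against 2.30 in KO18, 24.4 in KO19 and 0.869 to 7.91 in Control libraries, so KO19 was also above every Control library for both. Neither passed the edgeR test (adjusted p = 0.0948 and 0.0724). Without KO16 and KO20 the median of the adipocyte list went from 1.96 to -0.0105. The count of Pax8, whose promoter drives the rtTA transgene, rose to 145 ± 7.62 from 66.5 ± 18.5 CPM (log2 fold change 1.12, SE 0.23, adjusted p = 0.0112), and was named after its value was seen. Whether reads from the transgene, which the cKO mice alone carry, add to this count was not tested.

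Among the 35 splits of the 8 libraries into 4 and 4, only the genotype split gave 2170 changed genes (highest other 1 gene). It alone also gave 1824 genes changed at least 2-fold (highest other 1). Every other split puts cKO and Control libraries in the same set of 4. A genotype difference then adds to the spread within each set, which can lower the counts. Mixed splits therefore do not show what chance alone gives, and chance is not excluded by them for either count. The count of 19 lists with the preset correlation was reached by 9 of the 35 splits, with up to 24 lists in another split. A split with 24 lists set C10, C11, C13 and KO19 against C14, KO16, KO18 and KO20, which keeps part of the genotype difference. Mixed splits therefore neither exclude chance for this count nor show that chance gives it. By fry 21 lists passed in the genotype split and at most 1 in any other. The count of 5 lists with an estimated correlation was reached by 1 split, the genotype split, and the highest other count was 0. The same limit of mixed splits holds for this count and for that by fry.

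Lower proximal tubule expression could come from fewer proximal tubule cells with unchanged expression in each. The differences of 8 proximal tubule genes (Slc34a1, Slc34a3, Slc5a2, Slc6a19, Slc7a9, Lrp2, Cubn and Hnf4a) had an SD of 1.02 (log2). The highest other split, which mixes the groups, had 0.746. Fitted log2 fold changes were -4.25 for Slc34a3 and -2.84 for Slc34a1, and lay between -1.55 and -2.07 for the others. The 8 thus did not fall alike, but the unequal part rests on Slc34a1 and Slc34a3. Fewer cells as the cause for the other genes cannot be excluded by this test. A lower share of such cells as a part of the fall cannot be told apart from none. It would raise the marker lists of 6 other cell types alike, but the test measured only the spread of their mean differences. That SD was 0.28, a value reached by 4 of the 35 splits (highest other 0.302), and mixed splits hold genotype differences too. The means were 0.434 for loop of Henle, 0.0544 for principal cells and -0.0395 for intercalated cells. They were -0.0878 for distal convoluted and connecting tubule, -0.258 for podocytes and -0.371 for endothelium, so the lists did not all rise. Library trends on transcript length do not account for it, as all 29 enzymes and regulators that fell stayed lower with the trend removed. Loss of a single segment of the tubule and reduced expression within surviving cells stay open as hypotheses.

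The rise of p53 targets may follow from induced Cre recombinase and the transgenes rather than from loss of Xpr1. These cannot be told apart here, because 0 Control libraries carry the transgenes by their labels. Library trends on transcript length do not account for it, as all 12 targets that rose stayed higher with the trend removed. A response to loss of Xpr1 itself remains a hypothesis on the same footing.

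Of 13 mitochondrially encoded protein genes, 6 had at most 13 reads in any library (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l), while mt-Co1 had 555167 to 1511858. A candidate explanation is an identical nuclear copy that makes their reads non-unique: 5 of the 6 had an annotated pseudogene on chromosome 1 matching at least 99% of their length at over 99% identity, such as Gm28437 for mt-Co3 (24613189 to 24613971), and 0 of the 7 counted genes had a copy over 90% of their length. No annotated copy was found for mt-Atp8. Reads set aside as ambiguous between overlapping genes do not account for all 6, since 1 of them, mt-Atp8, is overlapped over more than 10% of its length on its strand.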
